A study of Pinus taeda with 24 samples.

How the data were processed

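Total RNA of 6 pools of 10 Pinus taeda seedlings was hybridised to 2-colour spotted cDNA arrays with 26496 spots. Seedlings had taken up 50 µl of water or of venom at 20 mg/ml through the cut stem and were frozen at 24 h or 48 h. Per the labels, Cy3 held the seedling RNA and Cy5 the common reference on every array, with no dye swap, so a dye effect specific to a probe is common to all pools and cancels in differences between them. Per the labels, each pool had 2 slides and each slide a first scan and a rescan, 12 slides and 24 arrays in all; the values did not bear out the rescans as second scans of the same slides. All arrays of a pool hold the same pooled RNA by these labels, so the 4 arrays of a pool were averaged and the pool was the replicate. Venom groups had 2 pools and water groups 1. The spread behind the p-values thus came from the 2 pairs of venom pools, moderated with the spread of other probes. No spread between water pools was measured, and the p-values assume that water pools vary as venom pools do.

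The deposited scanner tables hold the intensity of each spot and its local background in each channel, on a linear scale up to 65535, neither background-subtracted nor normalized. Images were quantified with ImaGene, per the deposited key to the columns, which also gives a combined quality flag. The authors' processed table holds log2 ratios of seedling over reference; its normalization is not given in the sources used here. Each of its columns correlated at 0.99954 or more with a loess-normalized log2 ratio computed here without background subtraction, its medians lay between -0.00694 and 0.0159, and its empty cells were the flagged spots. Its scale, centring and direction were settled by that comparison, and it was used as an alternative only.

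Background was corrected with normexp (offset 50) and log2 ratios were normalized by global loess within each array in limma 3.58.1 (R 4.3.3), with flagged spots given weight 0 and then left out. Between 4.3% and 8.37% of the spots per array were flagged. Control spots are not marked in the files used here and could not be left out as such. A probe was tested if every pool had at least 1 unflagged array; 25393 probes passed and 1103 did not. Group means of the 4 groups were fitted with lmFit and eBayes, with 2 residual degrees of freedom and 5.75 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts were venom against water at 24 h, at 48 h and over both times, 48 h against 24 h in venom, and the difference of the venom effect between times. No comparison has 3 pools in each group, so no regrouping of pools was counted.

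The procedure was tested on simulated data, 10 sets per comparison, each with 200 changed probes among 25393. Of these, 100 changed by 1 and 100 by 2 on the log2 scale. With variances drawn from the fitted prior, changes of 1 on the log2 scale were recovered for 55.2% of probes at 24 h, 50.6% at 48 h, 94.2% over both times and 84.5% for the change with time in venom. False calls were 5.57%, 5.38%, 5.22% and 5.49% of all calls. With the moderated variances observed in the data in place of the prior, 96.0%, 96.2%, 99.9% and 99.8% were recovered. These variances are already drawn toward the prior and differ less between probes, so this recovery may be too high. False calls with them were 9.09%, 9.96%, 8.8% and 10.1%, above the nominal level, and 12.0% for the difference between times. The counts of changed probes may thus hold more false calls than the threshold states. The simulations drew probes independently, with the same variance of a probe in every pool. They cannot show false calls from a more variable water pool, unequal spread at 24 h and 48 h or probes that vary together.

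The rule for named probes, fixed before the data were examined, took the largest changes past the threshold that ran the same way in every venom pool, among probes with a gene name. No probe has a name here, so the rule was applied over both times without that condition and limited to 2 probes in each direction; the 2 probes of the difference between times were named after their values were seen. The gene lists fixed beforehand could not be matched to probes, and the test planned on them was not made. Alternatives covered background correction, normalization, filters on dim or flagged spots, single scans and slides, slides as replicates, blocks, the authors' values, moderation, the threshold and leaving out each pool. Those on flagged spots, plate 39, array codes, plate medians, crossed pool numbers and a common water control were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9.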

Results

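Seedlings of loblolly pine (Pinus taeda) were cut at the soil line and took up either water or venom, the acid gland secretion that the woodwasp Sirex noctilio injects into pines when it lays its eggs. The question the design addresses is which transcripts change after the secretion is taken up, and whether they do so at 24 h and at 48 h. Each sample was a pool of 10 seedlings. There was 1 water pool and there were 2 venom pools at each time, 6 pools in all, and each pool was represented by 4 arrays. Every array set the seedling RNA, in Cy3, against a common reference RNA, in Cy5, mixed from shoot, root and callus tissue of other trees. Of 26496 spots, 25393 were measured in all 6 pools and tested. The median spot signal per array was 634 to 3167 in Cy3 and 508 to 5190 in Cy5, and the median signal over local background was 9.39 to 24.6 in Cy3 and 9.59 to 27.3 in Cy5. The number of pools limits the precision. Each water group was a single pool, which the tests assume to vary as the venom pools do. The files used here pair no probe with a gene name, so probes are given by their identifiers, whose first part is the plate of the clone library.

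At 24 h, 508 probes were higher and 505 were lower after venom than after water. The median log2 fold change was 0.95 among the higher probes and -0.88 among the lower ones, and 222 of the higher and 150 of the lower probes changed more than 2-fold. Probe 7.15.6 rose by 2.62 on the log2 scale (SE 0.32, adjusted p = 0.018), from a log2 ratio to the reference of -0.69 in the water pool to 1.92 ± 0.64 (SD, n = 2) in the venom pools. Probe 63.12.9 rose by 2.45 (SE 0.22, adjusted p = 0.0145). Probe 9.19.3, one of the transcripts far more abundant in seedlings than in the reference, had a log2 ratio of 4.84 in the water pool and of 2.57 ± 0.91 (SD, n = 2) in the venom pools, a log2 fold change of -2.28 (SE 0.43, adjusted p = 0.0348). Probe 9.16.8 had a log2 fold change of -1.96 (SE 0.31, adjusted p = 0.0241). In limma's moderated test, 5572 probes had an unadjusted p under 0.05, where uniform p-values would give 1270. The reference channel alone, with the same RNA on every array, gave 2169. A single channel and the ratio are unlike measures, and the seedling channel alone, normalized as the reference channel was, gave 4069. No probe passed in the seedling channel alone, without the reference, although 999 of the 1013 changed probes kept their direction there; none passed on the arrays labelled rescans, and 399 passed on the first scans.

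Among probes higher in seedlings than in the reference, more fell than rose. Of 1607 probes more than 2-fold above the reference in the 48 h water pool, 301 were lower and 28 were higher after venom at 24 h, and their median log2 fold change was -0.35. Of 1003 probes more than 2-fold below the reference in that pool, 22 were lower and 56 were higher. Their median log2 fold change was 0.0044, against -0.021 for all probes, so as a class they hardly moved. The 48 h water pool takes no part in the comparison at 24 h. It does enter the 48 h effect, with which the 24 h effect correlated across probes (Pearson 0.485), so the choice of these probes may favour falls. Probes were not also chosen by their ratio in the venom pools.

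At 48 h, 11 probes were higher and 5 were lower after venom, each by more than 2-fold. Among the 11 is probe 39.6.1 (log2 fold change 1.77, adjusted p = 0.0421 in limma's test), a dim, mostly flagged spot taken up below. Probes 7.15.6 and 63.12.9 had log2 fold changes of 1.92 (SE 0.32, adjusted p = 0.0661) and 1.70 (SE 0.22, adjusted p = 0.0541), and probes 9.19.3 and 9.16.8 had -0.98 (SE 0.43, adjusted p = 0.34) and -1.07 (SE 0.31, adjusted p = 0.165). These 4 values did not pass the threshold. An unadjusted p under 0.05 was reached by 3804 probes in the ratio. The like comparison is between single channels, with 1755 in the seedling channel alone and 1326 in the reference channel alone. In the reference channel 16 probes passed, 2 of them among those called in the ratio. The count of 16 in the ratio was unstable. It became 586 at an adjusted p under 0.10 and 524 without the dimmest 25% of the probes. Without background correction it was 365, and with median centring 0. In the seedling channel alone 3 probes passed, 0 of them among the 16, of which 14 kept their direction. Leaving out 1 venom pool raised the count of 16. A 24 h venom pool enters the 48 h comparison only through the spread shared by all groups, so leaving 1 out cannot move these fold changes. Across probes the 24 h venom pools were less alike (correlation 0.924) than the 48 h ones (0.956), whereas the tests assume 1 common spread.

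The effects at the 2 times, which share no pool, moved in the same direction for most probes changed at 24 h. Of the 508 probes higher at 24 h, 449 (88.4%) lay above 0 at 48 h, against 45.5% of all probes, with a median log2 fold change of 0.40. Of the 505 lower at 24 h, 456 (90.3%) lay below 0 at 48 h, against 54.5% of all probes, with a median of -0.59. In the other direction, 7 of the 11 probes higher at 48 h lay above 0 at 24 h. Of the 5 lower at 48 h, 4 lay below 0 at 24 h. Across probes, which are not independent replicates, the log2 fold changes at the 2 times had a Pearson correlation of 0.485 and a Spearman correlation of 0.393. The Pearson correlation was 0.181 in the seedling channel alone, 0.247 on slide 2 and 0.159 to 0.272 within single array codes. At both times 4 probes were higher, where independent lists would share 0.22, and 1 was lower, where they would share 0.0994. Both comparisons use the same estimated spread of a probe, so the lists would not be independent even without any change.

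**Figure D1:**
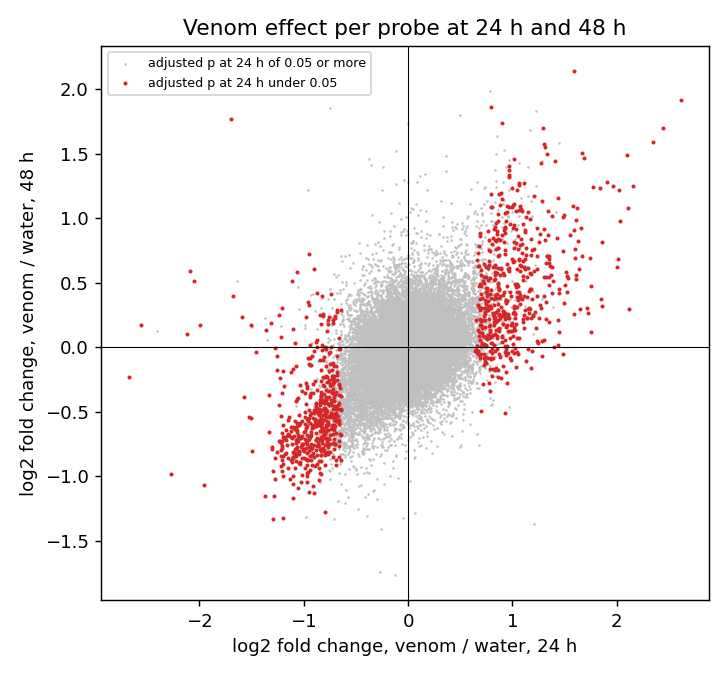
Log2 fold change of venom over water for each of 25393 probes at 24 h (horizontal axis) and 48 h (vertical axis); red points are the 1013 probes with an adjusted p under 0.05 at 24 h. Of the red points right of 0, 449 of 508 lie above 0 at 48 h, and of those left of 0, 456 of 505 lie below.

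Whether the venom effect itself differed between the times was tested directly. A larger signed log2 fold change at 48 h than at 24 h was found for 2 probes, named after their values were seen. They were 39.16.3 (difference 2.57, SE 0.21, adjusted p = 0.029) and 39.6.1 (difference 3.46, SE 0.28, adjusted p = 0.029). For 39.16.3 the effect was -2.05 at 24 h and 0.51 at 48 h, and for 39.6.1 it was -1.70 and 1.77. It changed sign in both probes, and the 48 h value of 39.16.3 did not pass. Both are dim spots of one quadrant of plate 39, unflagged on 8 and 9 of the 24 arrays and on only 1 array in the pool with the fewest. For 39.16.3 the difference was 0.47 without background correction and 0.41 with flagged spots kept, and for 39.6.1 it was 2.15 and 1.43, and none of these passed. For 39.16.3 and 39.6.1 it was 2.41 and 2.72 with plain background subtraction and 2.39 and 3.47 with median centring, and these did not pass either. For 39.6.1 the reference channel alone differed by -3.51 (SE 0.35, adjusted p = 0.0417) and the seedling channel alone by -0.63, so its difference in the ratio came from the reference channel. For 39.16.3 the seedling channel alone differed by 1.02, against 2.57 in the ratio, and did not pass. Among 10 simulated sets without any change, the highest number of such calls was 1 with variances from the fitted prior and 2 with the observed moderated variances. The different numbers of changed probes at 24 h and at 48 h do not by themselves show a different response. In this test 2220 probes had an unadjusted p under 0.05, little more than in the seedling channel alone (2130) or the reference channel alone (2040). A difference of 1 on the log2 scale was recovered for 3.9% of simulated probes with variances from the fitted prior. With the observed moderated variances, which may give too high a recovery, it was 54.4%. Without 1 venom pool the count was 0 (first 24 h pool), 21 (second 24 h pool), 7 (first 48 h pool) or 10 (second 48 h pool).

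Over both times, with each time given equal weight, 845 probes were higher and 1184 were lower after venom. Of these, 808 were higher and 1161 lower in all 4 venom pools, each set against the water pool of its time. The calls rest on the mean of these same differences, so this agreement is largely built in. Changes above 2-fold were found for 131 higher and 45 lower probes. Among probes that moved the same way in all 4 venom pools, the highest log2 fold changes were those of probe 7.15.6 (2.27, SE 0.22, 4.81-fold, adjusted p = 0.00658) and probe 63.12.9 (2.08, SE 0.15, 4.21-fold, adjusted p = 0.00658). The lowest were those of probe 9.19.3 (-1.63, SE 0.30, 3.09-fold lower, adjusted p = 0.0196) and probe 9.16.8 (-1.51, SE 0.22, 2.86-fold lower, adjusted p = 0.00907). No probe passed in the seedling channel alone, where 2012 of the 2029 kept their direction; 346 passed on the rescans. Arrays that carry the same array code in their labels deviated together, so each code was also tested as a batch holding 1 array of each pool: 20, 710, 13 and 1 probes passed within codes A1, A2, B1 and B2. With the code as a block over 24 arrays 4878 passed, but the estimated correlation within pools was -0.0333, so that fit counts the technical arrays of a pool as if they were replicates.

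**Figure D2:**
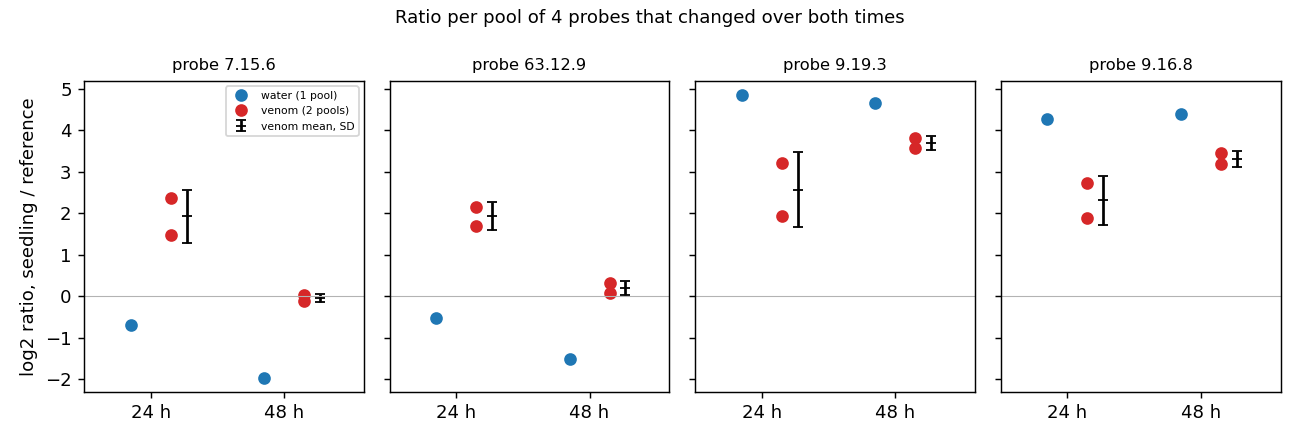
Log2 ratio of seedling over reference (vertical axis) per pool at 24 h and 48 h for probes 7.15.6, 63.12.9, 9.19.3 and 9.16.8, with the single water pool of each time in blue, both venom pools in red, and the mean and SD of the venom pools in black. At each time both venom pools lie above the water pool for 7.15.6 and 63.12.9 and below it for 9.19.3 and 9.16.8. The rule that named these probes required this.

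The changed probes were unevenly spread over the clone library. On plates 9 to 12, 282 of 1496 tested probes were lower over both times and 18 were higher, so that 20.1% changed. On plate 11 the share was 23.2%, with 81 of 86 changed probes lower. On plates 61 to 67, 275 of 2660 probes were lower and 140 were higher, 15.6% in all. Over all plates 7.99% of the tested probes changed.

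**Figure D3:**
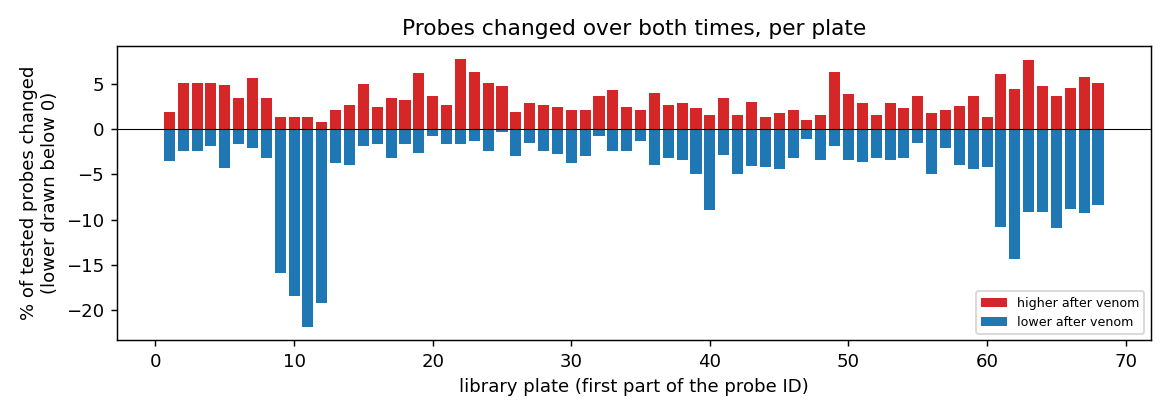
Percent of tested probes per library plate (horizontal axis) that were higher (red, above 0) or lower (blue, drawn below 0) after venom over both times. The longest bars are the lower probes of plates 9 to 12, where 282 of 1496 probes were lower.

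Between 24 h and 48 h after venom, 1339 probes rose and 1131 fell, 423 of them by more than 2-fold. Most of this change also ran in the same direction in the water pools: 1218 (91.0%) of the rising probes lay above 0 there, against 52.9% of all probes, and 973 (86.0%) of the falling ones lay below 0, against 47.1%. The median change in water was 0.47 for the rising and -0.34 for the falling probes, compared with 0.67 and -0.70 after venom. In water, a single pool against a single pool with the spread taken from the venom pools, 14 probes were called higher and 16 lower at 48 h, and 4093 had an unadjusted p under 0.05; these calls have no replicate check in water. Without 1 venom pool the count of 2470 became 1481 (first 24 h pool), 3046 (second 24 h pool), 1010 (first 48 h pool) or 1303 (second 48 h pool), and it was 48 in the seedling channel alone. Pools of one group were the most alike after venom, with a correlation across probes of 0.956 between the 48 h venom pools and 0.924 between the 24 h venom pools, and the least alike pair was the 48 h water pool and the first 24 h venom pool (0.706).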

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

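The tests of the rescans and of plate 39 were chosen after the data were examined, that of flagged spots before its own result was seen and the others after.

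The test of the difference of the venom effect between 48 h and 24 h called 2 probes, 1 of which differed in the reference channel rather than the seedling channel. Both lie in a quadrant of plate 39 that holds 96 spots, 61 of them tested. In this quadrant 50.7% of spot measurements were flagged, and the median log2 brightness was 7.77, against 10.2 on other plates. It held 13 probes changed at 24 h, all lower, among them 6 of the 10 largest falls. None of the 13 had 3 unflagged arrays in every pool, so a test restricted to such probes left 0 of them to examine and decides nothing; with flagged spots kept, 4 of the 13 still passed. Against the 48 h water pool, the quadrant's median log2 difference of the 24 h venom pools was -0.50 (bootstrap SD 0.13), compared with -0.66 against the 24 h water pool, which lies at the bound set for excluding the single 24 h water pool as the cause. The quadrant's median venom effect at 48 h was 0.19, opposite in direction. It also holds all 3 probes whose reference channel alone differed in the venom effect between times, although that channel holds the same RNA on every array. Dim, mostly flagged spots and the single 24 h water pool both remain open, and these values alone cannot separate them from a response to venom.

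Arrays labelled rescans resembled the first scan of their slide little more than they resembled another slide of the pool. A second scan of one slide should carry the same local background, yet the rank correlation of Cy3 background across spots was 0.167 between the scans of a slide and 0.246 between slides of a pool, a difference of -0.0794 (bootstrap SD 0.106), which argues against it. The log ratios correlated 0.0345 more within a slide. Arrays of different pools with the same code deviated together (mean correlation 0.113 after removing pool means, one-sided permutation p = 0.0001, the smallest that the permutations run can give), consistent with 4 sets of arrays processed together. No biological explanation was tested, since every set holds 1 array of each pool.

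Several quality measures were each tested in the 6 pools for an array far from the others of its pool, 24 tests in all on the same arrays. Of these tests, 3 singled out an array, and chance gives about 1 in 20. The median Cy3 signal was 3167 on array A1 of the second 24 h venom pool, where the others had 738 to 1114. The median Cy5 signal was 4113 on array A2 of the 24 h water pool (others 834 to 1078) and 5190 on array A1 of the 48 h water pool (others 813.5 to 1116.5). In the reference channel alone, which holds the same RNA on every array, 16 probes differed between venom and water at 48 h in limma's test, 2 of them also changed in the ratio, and 1326 had an unadjusted p under 0.05; at 24 h no probe did, with 2169 at an unadjusted p under 0.05. In the same channel 1 probe differed between 48 h and 24 h in venom, and 3 differed in the venom effect between times, all in the dim quadrant of plate 39; 1 of these, 39.6.1, is also 1 of the 2 probes called in the ratio.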

How the results depend on the processing

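For the first 4 comparisons below, the direction of the changed probes held better than their number. The alternatives reuse the arrays that gave the calls, and some change only the test or the threshold and leave every log2 fold change as it is. Kept directions are thus largely built in and give no independent support. Of 30 alternatives for 24 h, 14 gave a count within 1.5 times the 1013 reported; the same was true of 2 of 30 at 48 h, 18 of 30 over both times, 15 of 31 for the change with time in venom and 4 of 29 for the difference between times. Aquantile scaling and leaving out a water pool outside the comparison are not counted, since they cannot move it. In each of these alternatives at least 98.6% of the probes changed at 24 h that were still measured kept their sign, 87.5% at 48 h, 98.5% over both times and 98.2% with time in venom; for the 2 probes of the difference between times the lowest share was 50%. The cause of each shift below was not tested unless stated. Signal over background, as low as 9.39 on one array, limits dim probes. Alternatives on flagged spots, plate 39, array codes, plate medians, crossed numbers and a common water control were chosen after seeing the data.

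Background handling moved the counts at 48 h and for the difference between times: 365 and 0 without correction, 83 and 0 with plain subtraction, and 363 and 0 with the authors' processed values. Median centring gave 0 for both. The seedling channel alone gave 0 at 24 h, 3 at 48 h, 0 over both times, 48 with time and 0 for the difference; it moved the median of all probes at 24 h to -0.10, and for probe 39.6.1 it turned the difference between times to -0.63. Without the dimmest 25% of probes the counts were 1590 at 24 h, 524 at 48 h and 0 for the difference, with fewer probes tested. Only probes above background (signal at least 2 times the local background) gave 0 for the difference. Neither of the 2 probes of the difference was measured with these 2 filters, nor on single scans, slides or array codes, so those counts are of other probes. Where measured, 39.16.3 passed in 9 of 17 alternatives and 39.6.1 in 6 of 17. Moderation with trend and robust gave 8 at 48 h. An adjusted p under 0.10 gave 2196 at 24 h, 586 at 48 h, 3488 over both times and 4279 with time, by its construction.

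Fewer arrays gave fewer calls in most cases. First scans gave 399 at 24 h, 156 at 48 h, 1384 with time and 6 for the difference. Rescans gave 0 at 24 h, 1 at 48 h, 346 over both times, 754 with time and 0 for the difference. Slide 1 gave 53 at 24 h, 26 at 48 h, 958 over both times and 1285 with time; slide 2 gave 335, 32, 929 and 982, and 14 for the difference. In the order 24 h, 48 h, both times, time and difference, array code A1 gave 0, 45, 20, 0 and 1, code A2 gave 374, 91, 710, 402 and 58, code B1 gave 1, 1, 13, 387 and 1, and code B2 gave 0, 0, 1, 133 and 0.

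Slides taken as independent gave 1776 at 24 h, 715 at 48 h and 1 for the difference. With the pool as a random block, 12 slides gave 3414, 1606, 4344, 5272 and 113 in that order; the estimated correlation within pools was -0.231, below 0, which narrows the standard errors and makes these counts too large to rely on. The array code as a block over 24 arrays gave 4154, 2052, 4878, 5823 and 287, with a correlation of -0.0333, so it too counts technical arrays as replicates.

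The replicate block on the slide number gave 3089, 1405, 4130, 4932 and 56, with a correlation of -0.138. Differences between the slides correlated between pools from -0.0765 to 0.357 (median 0.121), over 0.1 in 10 of 15 pairs. Every pair over 0.1 was required for the numbers to count as pairing the slides, so the block was kept as an alternative, although arrays with the same code did deviate together. A replicate block on the number of the venom pools gave 1722 with time, and crossed numbers gave 3611.

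With flagged spots kept the difference gave 0. Requiring 3 unflagged arrays of 4 gave 72 at 48 h and 0 for the difference, and leaving out the dim quadrant of plate 39 gave 57 and 0; both remove the 2 probes of the difference. The mean of both water pools as the control gave 2115 at 24 h and 0 at 48 h. Subtracting plate medians gave 37 at 48 h. Leaving out 1 pool at a time gave 47 to 573 at 48 h (16 without the 24 h water pool, which that comparison does not use), 1010 to 3046 with time and 0 to 21 for the difference, while 24 h and both times stayed within 1.5 times. A lone pool is then assumed to vary like the other groups, and comparisons that need a water pool have no value without it. Over both times, probes 7.15.6, 63.12.9, 9.19.3 and 9.16.8 kept their direction in all 30 alternatives and passed in 27, 28, 25 and 27, with adjusted p-values up to 0.125, 0.102, 0.224 and 0.186. The correlation of the effects at 24 h and 48 h ranged from 0.159 to 0.56. Alternatives for the gene lists were not run, because no probe has a name.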

Other observations

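The tests in this part were chosen after the data were examined; those of plate medians and of the 48 h effect were set before their own results were seen, and those of brightness, of residual spread and of the ratio to the reference after related values were seen.

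Plates 9 to 12 and 61 to 67, singled out by their many calls, held 715 probes changed over both times among 4156. Their brightness would give 248.2 at the rate of other plates, a ratio of 2.88 (SD 0.11). The SDs in this paragraph treat probes as independent and leave out the spread between pools. With each plate's median subtracted in every pool, 81.5% (SD 1.45) of these calls remained, which argues against a shift of whole plates as the whole cause. The residual SD was no smaller there than elsewhere (ratio 1.03, SD 0.013). A candidate biological reading is that the clones of these plates come from tissue whose transcripts respond to venom, but the files used here do not give the plates' source libraries.

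Probes of plates 9 to 12 had a median log2 ratio to the reference of 0.44 in the water pools, 0.45 above that of other plates (SD 0.018, over resampled probes). The water pools also enter the calls that singled out these plates; in the venom pools, where a fall works against it, the median was still 0.32 above that of other plates, consistent with transcripts more abundant in seedling shoots than in the reference mixture. Among all probes more than 2-fold above the reference in the 48 h water pool, 301 were lower and 28 higher at 24 h, a ratio of 10.8. A 24 h water pool that was by chance rich in such transcripts could give this at 24 h alone. At 48 h, where that pool takes no part, the 1263 probes more than 2-fold above the reference in the 24 h water pool had a median effect of -0.21, against -0.026 for all probes. The bootstrap SD of -0.21, over probes, was 0.017 and leaves out the spread between pools. Of these probes, 67.4% lay below 0, against 54.5% of all probes. These 48 h values argue against the 24 h water pool as the whole cause. The 48 h effect also rests on a single water pool. Choosing probes by the 24 h water pool may favour falls too, since the effects at 24 h and 48 h correlated. The hypothesis that shoot-abundant transcripts as a class fall after venom was found and tested on the same data, and a different mix of shoot tissues in the venom and water pools remains open and was not tested.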
